A study of Mus musculus with 21 samples.

How the data were processed

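Poly(A)-enriched RNA from mouse hypothalamus was made into directional libraries and sequenced as paired-end reads, per the labels' protocols. The labels gave each of the 21 samples a genotype group (9 WT, 12 SH2B1adKO), a cohort date and a batch (A to E). The submitters' processing notes list the genome build GRCm38 and the tools FastQC 0.11.7, STAR 2.5.3a, StringTie 1.3.6 and DESeq2 1.22.2, without stating the role of each. The program that produced the gene table and its annotation release are not given in the sources used here.

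The authors deposited 1 table for the whole series, with a gene name, a gene identifier and a gene class for each row and 21 value columns, per the file headers. The gene class is text, and the other 2 descriptive columns are names, so none of these 3 is a measurement. The value columns are numbered, whereas the samples are titled with different numbers. A search of all sample labels for each column name and its number found 0 of the 21 columns, and all 21 were left out of the analysis. Columns were not assigned by their order, since no source used here states that it follows the order of the samples. They were not assigned by their values either, since assigning genotype from the level of the targeted gene would make any comparison of that gene circular. A few rows, Sh2b1 among them, were seen per column while the table was inspected, but none of their values was used. Column totals and levels over all columns would not need a genotype. They were left out too, as a choice, because no name ties a column to an individual sample. The table was deposited for this series and has as many value columns as there are samples. No test of expression was run.

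A comparison had been planned before the data were examined: a quasi-likelihood test per gene on the counts of all 21 libraries with batch as a term, the total count of Sh2b1, and tests of 32 gene lists covering feeding peptides, leptin signalling, synapse, clock, stress, metabolic and cell type marker genes. The genes to be named would have been Sh2b1 and its family, a fixed panel of feeding and hypothalamic genes, and genes or list members past the test's threshold. Had many genes passed, only those with the smallest p-values and the same direction in most batches were to be named. Had few passed, the closest genes that did not pass were to be given as values. Lists called as a whole were also to have their members with the smallest p-values named. None of these tests was run, and no list has a result. The lists contain 687 different genes, of which 685 have a row in the table under the symbol as written.

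From the labels, samples were tabulated by group, batch and cohort date, and the residual degrees of freedom and the relative standard error of the genotype effect were computed from the design matrices. Gene identifiers in the table were matched, without version suffix, to GENCODE release M21 on GRCm38, and 53620 of the 53803 rows matched. Transcripts of Sh2b1 were taken from the same annotation. Codons were counted as coding bases divided by the codon length, with the stop codon left out, and the end of a coding sequence is the last coding base before the stop codon. Positions are 1-based. Exon bases of transcripts were compared position by position. These steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.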

Results

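Hypothalamic mRNA was profiled in 21 mice, 9 wild-type controls and 12 mutants that lack the alpha and delta isoforms of Sh2b1. Sh2b1 encodes an adapter protein that binds activated JAK2 and several receptor tyrosine kinases, and its isoforms differ in their C-terminal tails. The design implies 1 comparison, mutant against wild type, whose purpose was to find genes with altered expression in the mutant hypothalamus. That comparison was not made here. The deposited gene count table names its 21 library columns by numbers that occur in none of the sample labels, so no column could be assigned to a mouse or to a genotype by name. Values from columns that could not be tied to an individual sample were left out altogether, so expression levels and sequencing depth are not reported either. What follows is limited to the sampling design, the gene set of the table and the annotated structure of the targeted gene.

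Both genotypes were present in each of the 5 batches given in the labels. Batches A, B and D each held 2 wild-type and 2 mutant mice. Batch C held 1 wild-type and 2 mutant mice, and batch E held 2 wild-type and 4 mutant mice. The labels also gave 6 cohort dates, and each of them likewise included both genotypes. The cohorts were less even than the batches. The cohort of 8/6/2019 (month/day/year) had 3 wild-type mice and 1 mutant, whereas the cohorts of 7/12/2019 and 12/20/2019 each had 1 wild-type mouse and 3 mutants. Genotype was also partly tied to cohort date within batches. In batch A both wild-type mice were from 8/6/2019. Both mutants of batch B were from 7/12/2019, and both mutants of batch D were from 4/12/2019. A batch term alone does not adjust for cohort date within a batch. With batch as a term, the genotype effect could be estimated with 15 residual degrees of freedom.

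The targeted gene, Sh2b1 (ENSMUSG00000030733), has a row in the table. It lies on the minus strand of chromosome 7 between positions 126466994 and 126475424 of GRCm38, according to GENCODE release M21. No other annotated gene overlaps it. The nearest protein-coding genes are Atp2a1, which encodes a calcium pump of the sarcoplasmic reticulum and starts on the same strand, with 3885 bases between it and the 3′ end of Sh2b1, and Tufm, which encodes the mitochondrial elongation factor Tu and starts on the opposite strand, with 11936 bases between it and the 5′ end of Sh2b1.

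GENCODE lists 9 transcripts of Sh2b1, of which 7 are classed as protein-coding. The 6 full-length coding transcripts encode proteins of 4 lengths. Sh2b1-205 encodes 756 codons, Sh2b1-204 and Sh2b1-206 encode 724, Sh2b1-201 encodes 682, and Sh2b1-202 and Sh2b1-203 encode 670. These lengths are those generally given for the mouse alpha, delta, gamma and beta proteins, in that order, although the annotation itself does not use the Greek names. The alpha-length and delta-length transcripts skip a coding block of 100 bases, at positions 126467950 to 126468049, that the beta-length and gamma-length transcripts include. Their reading frames then end further into the last exon, at position 126467400 for the alpha-length transcript and 126467549 for the delta-length transcripts. The coding sequence of the beta-length transcripts ends at 126467758, and that of the gamma-length transcript ends at 126467951, inside the 100-base block. The block alone does not account for these ends, since the alpha-length and delta-length transcripts both skip it but end at different positions. Those 2 ends lie further apart than the coding lengths differ, at 2268 bases for alpha-length and 2172 for delta-length. The delta-length transcripts therefore include other coding bases that the alpha-length transcript lacks.

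**Figure D1:**
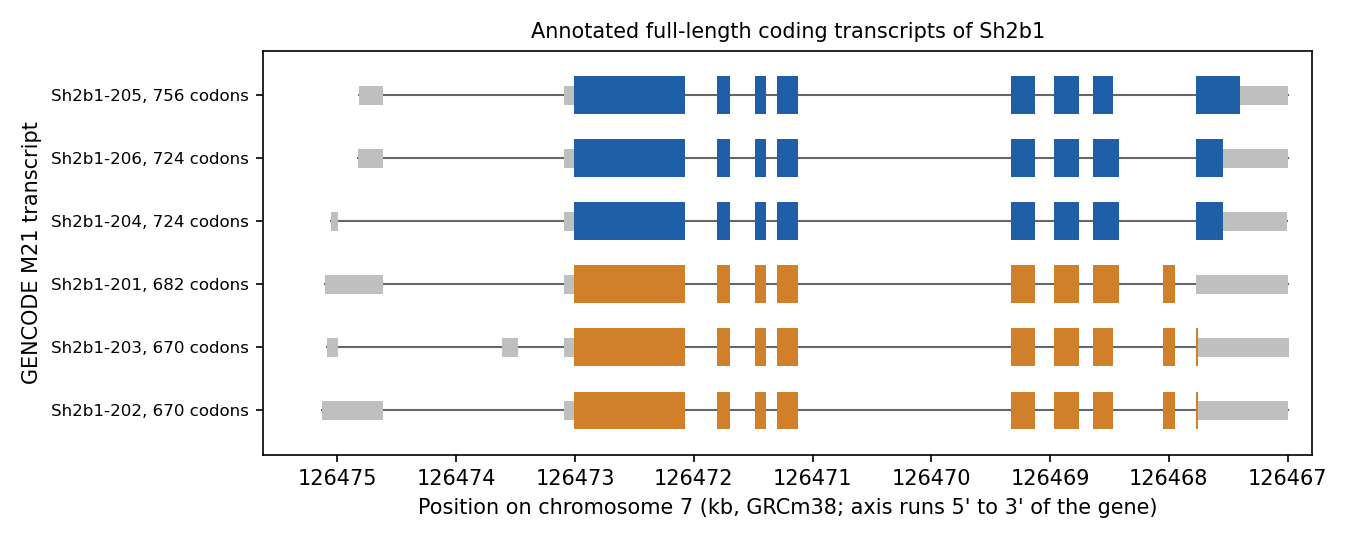
Exon structure of the 6 full-length coding transcripts of Sh2b1 on chromosome 7 (x axis, position in kb on GRCm38, running 5′ to 3′ of the gene; y axis, GENCODE M21 transcript and its number of codons). Tall boxes are coding sequence (blue for the transcripts of 756 and 724 codons, orange for those of 682 and 670 codons), low grey boxes are untranslated exon sequence and lines are introns; the 3 blue transcripts lack the 100-base block that the 3 orange transcripts contain.

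The exons of these 6 transcripts cover 3559 bases. Of these, 3066 bases (86.1%) are shared by the alpha-length and delta-length transcripts and the other forms. The remaining 493 bases belong to the beta-length and gamma-length transcripts alone, and 0 bases belong to the alpha-length and delta-length transcripts alone. Of the 493, only the 100 bases of the skipped block are coding. The others lie in untranslated blocks of 171, 137, 80 and 5 bases. The blocks of 80 and 5 bases lie beyond the annotated outer ends of the alpha-length and delta-length transcripts. They therefore reflect where the transcripts were annotated to begin and end. Of the bases coding in either set of transcripts, 1963 (81.1%) are coding in both. The alpha-length and delta-length reading frames extend over last-exon positions that are untranslated in the other forms. The comparison of exon and coding bases is by genomic position, so bases coding in both sets need not be read in the same frame. It also leaves out exon junctions, which differ at least where the 100-base block is skipped. It pools alpha-length with delta-length and beta-length with gamma-length transcripts, so differences within each pair are not resolved. A count for the whole Sh2b1 gene does not separate its isoforms.

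The table has 53803 gene rows. Protein-coding genes account for 22006 rows (40.9%), processed pseudogenes for 9117 and lincRNAs for 5372. No gene class is given for 129 rows and no gene name for 129 rows, and whether these are the same rows was not checked. Apart from 53801 rows with Ensembl mouse gene identifiers, 2 rows have none and are identified as Cre and Gfp_L10a. A row by itself does not show that the mice carry either sequence, and no count for these rows is reported here.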

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

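No expression result could be recomputed under another setting, because none was obtained. Other choices of normalization, filtering, left-out libraries and batches, surrogate variables and test had been foreseen and were not run. No paired analysis was possible because no column of values could be matched to a sample, and so to its batch or cohort; the labels give no number that pairs mice across genotypes. What could be compared is the design itself. The residual degrees of freedom, 15 with batch as a term, were 19 without a batch term, 14 with cohort date in place of batch and 12 with batch and cohort date together. The standard error of the genotype effect, for a given residual spread, was 0.986 times that of the batch design without a batch term, 1.08 times with cohort date and 1.13 times with both terms, and the genotype effect could be estimated in all 4 designs. Matching older gene symbols as well, an alternative chosen after seeing the data, raised the number of list genes with a row in the table from 685 to 687.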
